A study of Mus musculus with 15 samples.

How the data were processed

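Hepatocyte chromatin of 15 mice was profiled by srHC-seq, with 5 mice in each of 3 groups: P14 wild type, P14 with loss of Ezh1 and Ezh2, and 2-month wild type. Per the labels' protocols, crosslinked chromatin was sonicated, and long and short DNA fragments were separated with beads and sequenced. Per the submitters' processing notes, the tools were bcl2fastq 2.19.0.316, STAR 2.4.2a and bedtools, and the genome build was mm9. The program that called the domains and its thresholds are not stated there. The deposited data are 9 lists of genome intervals, 1 for each of the classes het, int and euch in each of the 3 groups. Per the sample descriptions, each list is named under all 5 samples of its group, males and females, except that 1 female of the 2-month group does not name the euch list. Each list was therefore read as a pool of its whole group, which is an inference and is less certain for euch at 2 months. The deposited intervals carry a class letter, and their score column is 0 throughout, so they hold no signal and no depth.

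The lists were checked before use. Within each group the 3 lists tiled the genome, with no base in 2 classes and no neighbouring intervals of one class, and edges lay on a grid of 2 kb except at chromosome ends. In the knockout, 2 bases of chromosome Y were in no list. The 14 unplaced contigs (70.9 Mb) and chromosome Y beyond position 2904001 were int throughout. The autosomes held 32 runs of at least 100 kb, 72.8 Mb in all, that were int in all 3 groups, which is 24.8% of the int bases of the P14 wild type. Such runs include the chromosome starts and can hold sequence to which no read maps, so a call of int there says nothing about chromatin. They were kept, and leaving them out was one of the alternatives.

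Maps were read at a resolution of 1 kb with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9. Coordinates are 1-based. Autosomes were used for the main values because the groups differed in their mix of sexes, and chromosome X was handled apart. For each group, the number, length and genome share of domains were computed. For each comparison, bases were cross-tabulated by class in both maps. A move from het to int or euch, or from int to euch, was counted as towards euch, and the reverse as towards het. Chance levels for the share of bases with the same class came from 200 rotations of one map within each chromosome by at least 5 Mb. The openness score of a window is the share of its bases in euch minus the share in het. Windows of 1 Mb with at least 50% of their length present were used, 2473 in all. Intervals at 95% were drawn by resampling stretches of 10 Mb 1000 times. No p-value was computed, since each group has a single map and neither windows nor chromosomes are replicates.

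The overlap of the age and knockout changes was computed among bases of one P14 wild-type class and set against the product of the 2 shares. Its level without any effect was taken from 3 simulated sets of maps. Each map was the smoothed P14 wild-type map plus independent noise over a few kb, of equal size in all 3 maps. The noise was scaled so that 72.7% of bases had the same class, close to the observed 72.6%. The procedure was also tested on simulated data in which the knockout shift was 0.5 of the age shift, and returned a slope of 0.496. With no change in either comparison the simulated slope was 0.507, so the slope alone does not measure the size of a shared effect.

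Comparisons, the rule for naming regions and most alternatives were chosen before the data were examined. The rule named, for each comparison, the 10 windows with the largest rise, the 10 with the largest fall, and the 10 longest stretches from het to euch and from euch to het. Alternatives were adding chromosome X, dropping domains under 5 kb, dropping bases within 1 or 5 kb of a P14 wild-type domain edge, counting whole domains at 50% or 80% of their bases, and leaving out each autosome. Added after the data had been seen were leaving out the shared int runs, windows of 500 kb and 5 Mb, and alternate blocks of 20 kb. The correlation and slope of window changes were themselves added to the planned overlap after the data had been seen. The 23 gene lists fixed beforehand, and the promoters and genes they hold, were not analysed here because the only annotation at hand was for another genome build. Regions are therefore given by position alone.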

Results

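Chromatin of mouse hepatocytes was mapped by srHC-seq, an assay in which crosslinked chromatin is sonicated and its DNA fragments are separated by size, so that sonication-resistant heterochromatin can be told from open chromatin. There were 15 samples in 3 groups of 5. The first group came from wild-type mice at postnatal day 14 (P14; 3 males and 2 females). The second came from P14 mice whose hepatocytes lacked Ezh1 and Ezh2 (2 males and 3 females), the genes of the catalytic subunits of PRC2, the complex that methylates lysine 27 of histone H3. The third came from wild-type mice at 2 months of age (2 males and 3 females). Each group was represented by 1 genome map, read as a pool of its samples, in which every stretch of the mm9 genome was called het (closed), int (intermediate) or euch (open). The maps held 131395 domains in P14 wild-type, 120579 in P14 knockout and 94111 in 2-month wild-type hepatocytes, each over 2725.77 Mb. They carried no read counts, so the depth behind each call is unknown. With 1 map per group there was no replicate to test a difference against. All intervals are 95% bootstrap intervals over stretches of 10 Mb and cover variation along the genome, not variation between animals.

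The het class covered a similar share of the autosomes in all 3 groups, and so did the euch class. There were fewer domains at 2 months, however, and long domains made up more of the genome. The het class covered 45.4% of autosomal bases in P14 wild-type, 46.0% in P14 knockout and 46.2% in 2-month hepatocytes. The euch class covered 42.7%, 42.4% and 43.0%, and the int class 11.9%, 11.5% and 10.7%, in the same order. How calls were scaled in each map is unknown, so near-equal shares may come from the calling and do not show equal amounts. Het bases, a similar share of the autosomes at both ages, were divided into 41439 domains at P14 and 28510 at 2 months, 31.2% fewer. Euch domains numbered 40522 and 25999, 35.8% fewer. The mean length of a het domain was 27.1 kb at P14 and 40.1 kb at 2 months, and that of a euch domain was 26.1 and 40.9 kb. The N50, the length at or above which 50% of the bases of a class lay, was 46 kb for het at P14 and 84 kb at 2 months. For euch it was 52 and 112 kb. The median domain differed less, at 14 and 18 kb for het and 12 and 14 kb for euch. Knockout hepatocytes of P14 lay between the others, with 38014 het and 36222 euch domains, 8.27% and 10.6% fewer than in the wild type of their age. Their mean lengths were 29.9 kb for het and 29.0 kb for euch.

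Very long domains differed in number as well. Het domains of at least 200 kb numbered 463 in P14 wild-type, 572 in P14 knockout and 824 in 2-month hepatocytes. Euch domains of that length numbered 453, 591 and 1064. Of the 1064 long euch domains at 2 months, 90.0% covered at least 2 separate euch domains of the P14 wild type, with a median of 4. Of the 824 long het domains, 81.8% did so for het, also with a median of 4. In the knockout, 71.2% of long het and 68.5% of long euch domains spanned at least 2 domains of the P14 wild type. The P14 wild-type map held 16.4 euch and 16.8 het domains per Mb, so long stretches span several by length alone. No level without joining was computed, so these counts do not show that domains were joined. The longest het domain at 2 months ran for 2628 kb on chromosome 7, from 32134001 to 34762000, and the longest in the knockout for 2844 kb over nearly the same stretch, from 31996001 to 34840000. The longest euch domain at 2 months ran for 1398 kb on chromosome 19, from 36390001 to 37788000.

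**Figure D1:**
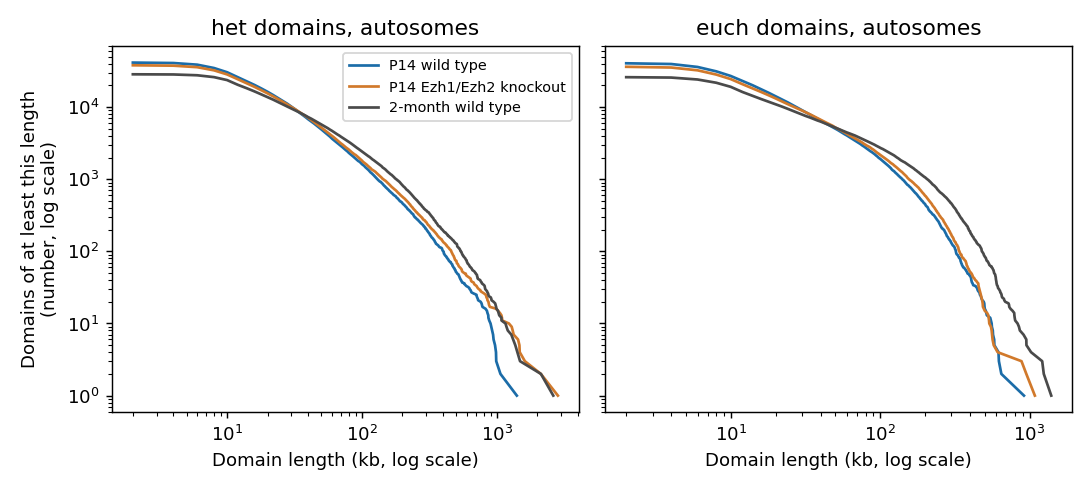
Number of autosomal het and euch domains (y axis, log scale) of at least a given length in kb (x axis, log scale) in the pooled map of each group. The 2-month line starts lowest and is highest at 200 kb, with 824 het and 1064 euch domains of at least 200 kb against 463 and 453 in P14 wild-type hepatocytes, and the knockout lies between them at that length.

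The comparison of P14 with 2-month wild-type hepatocytes addresses how closed and open chromatin is rearranged as the liver matures after birth. Of all autosomal bases, 27.4% (interval 26.6 to 28.2), or 676 Mb, had another class at 2 months. Counted by bases, calls moved both ways in nearly equal amounts, which a calling that fixes class shares would also give. Bases that moved towards euch made up 13.6% and those that moved towards het 13.7%, a net of -0.0955 percentage points (-1.58 to 1.47). These values depend on how changes are counted: the share was 13.1% without bases within 5 kb of a P14 wild-type domain edge, and 52.7% when whole domains were counted, with a net then of -5.89 points. From het to euch went 159 Mb, 14.2% of the het bases of P14, and from euch to het went 170 Mb, 16.1% of the euch bases. The class was the same at both ages for 72.6% of bases (Cohen's kappa 0.539). When one map was rotated along each chromosome 200 times, the same share averaged 40.7% and reached at most 41.8%.

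Whole regions moved in one direction. Openness was scored as the euch share minus the het share of a window of 1 Mb, from -1 for fully closed to 1 for fully open. The largest fall was on chromosome 5 from 12000001 to 13000000, where the score was 0.286 at P14 and -0.854 at 2 months. In that window euch covered 572 kb at P14 and 30 kb at 2 months, and het covered 286 and 884 kb. Next came chromosome 6 from 61000001 to 62000000, with 0.274 at P14 and -0.818 at 2 months, and chromosome 2 from 46000001 to 47000000, with 0.338 and -0.726. The 10 largest falls, on 7 chromosomes, ranged from -1.14 to -0.908. The largest rise was at the far end of chromosome 7, from 151000001 to 152000000, where the score was -0.566 at P14 and 0.296 at 2 months. Chromosome 16 from 11000001 to 12000000 had -0.008 and 0.788, and chromosome 12 from 111000001 to 112000000 had -0.204 and 0.578. The 10 largest rises lay on 10 different chromosomes and ranged from 0.696 to 0.862. Of 2473 windows, 214 had a score lower by more than 0.5 at 2 months and 48 had one higher by more than 0.5.

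Among autosomes, chromosome 19 opened most with age. Its euch share was 49.0% at P14 and 60.0% at 2 months, and its het share was 37.5% and 26.6%. Chromosome 11 came next, with a euch share of 41.6% and 48.3%. Of the autosomes, chromosome 3 closed most, with a euch share of 48.2% and 43.3%, followed by chromosome 1, with 43.2% and 39.9%. The openness score was higher at 2 months on 8 autosomes and lower on 11.

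**Figure D2:**
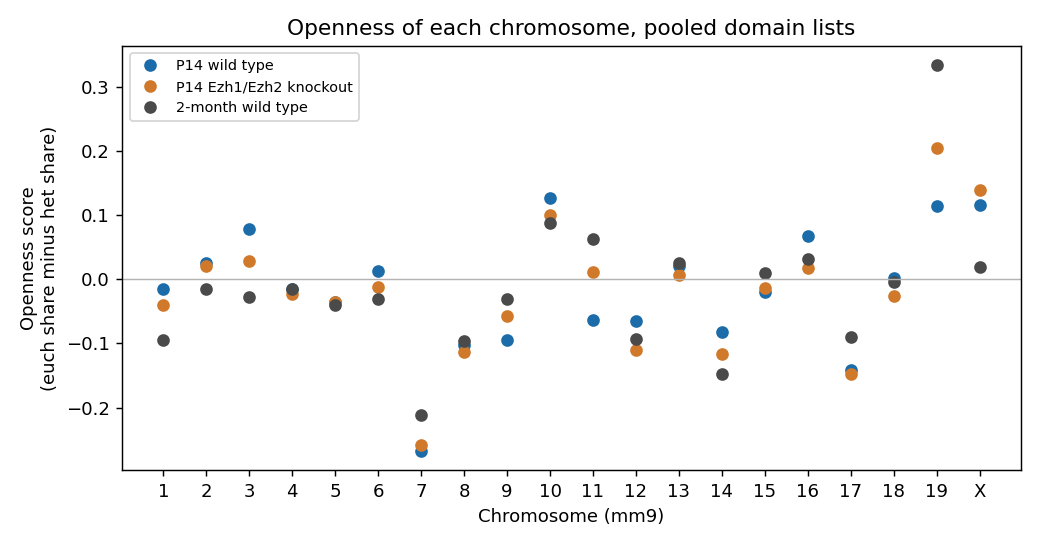
Openness score (euch share minus het share, y axis) of each autosome and of X (x axis), 1 point per pooled map. On chromosome 19 the scores are 0.115 in P14 wild-type, 0.204 in P14 knockout and 0.334 in 2-month hepatocytes.

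Single stretches that went from one extreme to the other were short, with a median of 6 kb in both directions. The longest that went from het to euch was 118 kb on chromosome 11, from 27750001 to 27868000. In the P14 knockout 81.4% of it was still het. Among the 10 longest such stretches, 9 were mostly het in the knockout. The longest that went from euch to het was 84 kb on chromosome 16, from 65340001 to 65424000, and 76.2% of it was het in the knockout too. Among the 10 longest in this direction, 4 were mostly het and 3 mostly euch in the knockout. Both comparisons start from the same P14 wild-type map, whose errors favour agreement between them. Long domains kept their class. Of P14 wild-type domains of at least 200 kb, 99.8% of both het and euch domains had at least 50% of their bases in the same class at 2 months. Of those under 10 kb, 47.4% of het and 46.6% of euch domains did. The age difference had no replicate check, and the males and females were not in equal proportion at the 2 ages, so the main values are autosomal. Leaving out X does not remove any sex difference on autosomes, which was not tested.

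The comparison of P14 knockout with P14 wild-type hepatocytes addresses what loss of Ezh1 and Ezh2 does to the map at a fixed age. Of autosomal bases, 24.6% (23.9 to 25.3), or 608 Mb, had another class in the knockout. Bases called more open made up 12.1% and bases called more closed 12.5%, a net of -0.439 percentage points (-1.29 to 0.434). A net opening of the autosomes cannot be judged from this value, since class shares may be fixed by the calling within each map. The share was 11.0%, with a net of 0.664 points, without bases within 5 kb of a wild-type domain edge, and 46.4%, with a net of -7.10 points, when whole domains were counted. From het to euch went 124 Mb, 11.0% of wild-type het bases, and from euch to het 135 Mb, 12.8% of wild-type euch bases. The class was the same in 75.4% of bases (kappa 0.587), against an average of 40.5% and a highest value of 41.3% over 200 rotations.

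Window changes in the knockout were smaller than with age, with a standard deviation of 0.179 against 0.315. The largest gain of openness was on chromosome 11 from 96000001 to 97000000, where the score was -0.04 in wild-type and 0.514 in knockout hepatocytes of P14. The same window stood at -0.008 at 2 months. Chromosome 11 from 94000001 to 95000000 had -0.116 in the wild type and 0.324 in the knockout. Chromosome 9 from 43000001 to 44000000 had -0.258 and 0.164. Chromosome 12 from 28000001 to 29000000 had -0.262 and 0.158. The 10 largest gains ranged from 0.388 to 0.554. The largest loss was on chromosome 2 from 40000001 to 41000000, with 0.254 in the wild type and -0.386 in the knockout. Chromosome 12 from 98000001 to 99000000 had -0.066 and -0.666, and chromosome 16 from 40000001 to 41000000 had 0.21 and -0.378. The 10 largest losses ranged from -0.64 to -0.54, and 19 windows against 1 passed a change of 0.5 in the direction of closing.

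**Figure D3:**
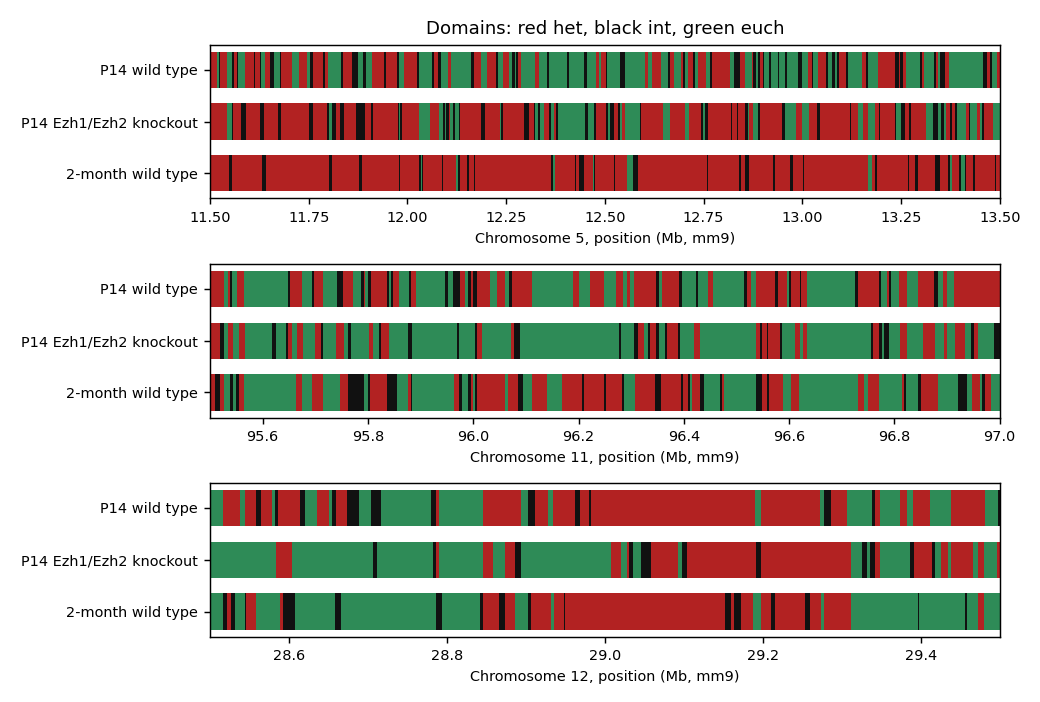
Class of each base (red het, black int, green euch) along 3 regions of the mm9 genome (x axis, position in Mb) in the pooled map of each group. On chromosome 5 from 12000001 to 13000000 euch falls from 572 kb in P14 wild-type to 300 kb in P14 knockout and 30 kb in 2-month hepatocytes. On chromosome 12 from 28900001 to 29000000 euch covers 100 kb in the knockout, 8 kb in P14 wild-type and 6 kb in 2-month hepatocytes. On chromosome 11 from 96000001 to 96300000 it covers 268, 156 and 70 kb in the same order. Both of these stretches were chosen after their values had been seen. Elsewhere in the regions of chromosomes 11 and 12, some windows of 100 kb are less open in the knockout than at 2 months.

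Among autosomes, chromosomes 19 and 11 again had the largest gains of openness, with euch shares of 53.4% and 45.3% in the knockout against 49.0% and 41.6% in the wild type. Chromosome 3 had 45.7% against 48.2%. The openness score was higher in the knockout on 6 autosomes and lower on 13. The longest stretch from het to euch was 52 kb on chromosome 10, from 79652001 to 79704000, and the longest from euch to het was 70 kb on chromosome 2, from 57312001 to 57382000. At 2 months 69.2% of the former was euch and 94.3% of the latter was het. All 10 of the longest stretches that went from euch to het in the knockout were mostly het at 2 months as well. Of the 10 longest from het to euch, 7 were mostly euch and 2 mostly het at 2 months. All these stretches were picked for differing from the P14 wild-type map, so errors of that map favour such agreement. No level without change was computed for them. Domains of at least 200 kb kept their class in 99.8% (het) and 100% (euch) of cases, and those under 10 kb in 55.1% and 53.9%. The difference between genotypes had no replicate check, and the mix of sexes differed between the 2 pools.

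The series also allows the question of whether the knockout moved the P14 map the way age did. Region by region, both sets of changes ran in parallel. Over the 2473 autosomal windows, the change in the knockout correlated with the change with age (Pearson r = 0.828, interval 0.810 to 0.845; Spearman rho 0.817), with a slope of 0.471 (0.452 to 0.487). The direction was the same in 80.8% of windows. Of the 214 windows that were lower by more than 0.5 at 2 months, 211 were lower in the knockout too. Of the 48 that were higher, 47 were higher. These windows were picked by their distance from the shared P14 wild-type map, and no level without change is available for both counts. The knockout score lay between those of the other groups in 64.6% of windows, and each of the other groups lay in the middle in 15.4%. On chromosome 5 from 12000001 to 13000000, for example, the scores were 0.286 in P14 wild-type, -0.26 in P14 knockout and -0.854 in 2-month hepatocytes. By chromosome, the direction was the same on 15 of 19 autosomes, the exceptions being 5, 8, 13 and 17. These windows lie along 1 genome and are not independent replicates.

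**Figure D4:**
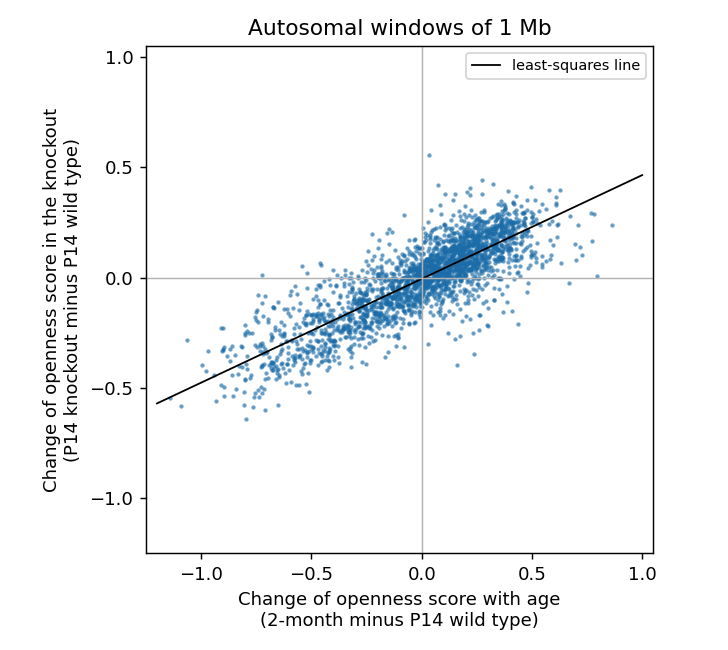
Change of openness score with age (x axis, 2-month minus P14 wild type) against the change in the knockout (y axis, P14 knockout minus P14 wild type), 1 point per autosomal window of 1 Mb (2473 windows). The line is the least-squares fit, with a slope of 0.471.

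Both comparisons use the P14 wild-type map, so its chance errors enter both. In simulated maps with no change in either comparison, the direction was the same in 65.9% of windows (observed 80.8%). The knockout lay in the middle in 32.7% (observed 64.6%), and no window changed by more than 0.5. The simulated noise was local, over a few kb, and largely averaged out within a window. The standard deviation of simulated age changes was 0.0723, against 0.315 observed. These levels thus leave out differences between maps over longer stretches, and exceeding them does not rule such differences out. The direction was the same on up to 14 of 19 simulated autosomes, so the observed 15 is little above that level. In the same simulated maps, the correlation was 0.503 and the covariance 0.00265, against an observed covariance of 0.0467. The simulated slope was 0.507 with no change and 0.496 with a knockout shift of 0.5 of the age shift, so the observed slope does not tell these apart. When the 2 changes were taken from alternate blocks of 20 kb that share no base, the observed correlation was 0.751 (0.729 to 0.772) and the simulated one 0.126. The highest of 1000 rotations of one set of changes, along the autosomes joined end to end, was 0.111. A rotation also breaks the link through the shared control, so this value does not measure that link. The control could not be split, since its 5 animals are in 1 map, and part of the excess may come from the shared control.

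Base by base, the overlap ratio did not separate a shared effect from a shared control. Among het bases of the P14 wild type, 22.3% were less closed at 2 months, 19.4% were less closed in the knockout and 10.9% in both, against 4.31% for independent changes. That is a ratio of 2.54, and simulated maps with no change gave 2.31. Among euch bases, 22.7%, 20.1% and 13.3% were less open, against 4.55% for independent changes, a ratio of 2.93 where simulated maps gave 2.34. Simulated maps with a knockout shift of 0.5 of the age shift gave 2.16 for het and 2.16 for euch bases. In those maps 67.2% of bases had the same class at both ages, against 72.7% without change, so the 2 simulations are not matched. The knockout map had the same class as the 2-month map in 76.8% of autosomal bases, more than either shared with the P14 wild type. Only the P14 wild type differed from the other 2 maps in 11.8% of bases, only the 2-month map in 10.4% and only the knockout map in 7.60%. All 3 maps had the same class in 65.0%.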

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

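The test of the sex mix was chosen after the X chromosome values had been seen. The main comparisons leave out chromosome X, and on X the 2-month map differed from both P14 maps. Its het share was 41.7% at 2 months, 37.5% in P14 wild-type and 36.7% in P14 knockout hepatocytes, and its euch share was 43.6%, 49.1% and 50.7%. The het share was higher at 2 months by 4.16 percentage points (1.08 to 7.35), while the knockout differed by -0.757 points (-2.57 to 1.11), both against the P14 wild type. By autosome, the change of het share with age ran from -10.9 points on chromosome 19 to 5.83 points on chromosome 3. The rise on X lay within that range, so its size was not particular to X.

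One X chromosome of each female is inactive and compact, so a pool with more females could hold more het on X. The 2-month and the knockout pools both had 3 females of 5, and their changes differed by 4.92 percentage points (2.90 to 6.82). The knockout pool also lacked Ezh1 and Ezh2, and an effect of that loss on X could offset the sex mix, so the sex mix and age cannot be told apart here. Unequal numbers of reads per animal within a pool were not tested, and stay open. A difference of X chromatin with age also stays open as a hypothesis.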

How the results depend on the processing

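No paired analysis was possible because the lists pool the replicates of each condition, and no replicate could be left out for that reason. The correlation and slope of window changes, and the alternatives on shared int runs, window size and alternate blocks, were chosen after the data had been seen. Only the correlation and slope of window changes could have been called reversed, and neither was. The other results cannot be negative, have intervals that include 0 or, for domain counts, were checked for size alone. Leaving out each autosome in turn moved none of the 14 results beyond its interval (domain counts beyond 1.5 times), nor did adding X. The correlation of window changes ranged from 0.823 to 0.832 and the net age change from -0.518 to 0.335 points. With domains of at least 5 kb alone, 10 of 14 results stayed within these limits. The euch share change with age, reported as 0.284 points (-1.03 to 1.43), was -0.0351 points there. It was -0.0799 points with X added and -0.0521 points without chromosome 11. Joining across gaps, the classified span of each chromosome as denominator and double counting could change nothing, since the lists tile the genome without overlap. The promoter alternatives were not run. Depth limits cannot be given.

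The share of bases with another class was lower without domain edges or short domains and higher when whole domains were counted. For age it was 22.9% with domains of at least 5 kb, 23.9% and 13.1% without bases within 1 and 5 kb of an edge, and 28.2% without shared int runs. For the knockout it was 20.0%, 21.2%, 11.0% and 25.4%. Counted as whole domains it was 52.7% (at 50% of bases) and 52.4% (at 80%) for age, and 46.4% under both for the knockout. Short domains then weigh as much as long ones, and int domains are counted too. With age 36.2% of int bases kept their class. How much short and int domains each add was not tested. The net change in whole-domain counts was -5.89 and -4.97 percentage points for age and -7.10 and -5.58 for the knockout. For the knockout away from edges by 5 kb it was 0.664. That sign differs from the reported one, whose interval includes 0, and the cause was not tested.

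The overlap ratio for het bases was 2.95 with domains of at least 5 kb, 2.66 without bases within 1 kb of an edge and 3.24 without those within 5 kb. For euch bases it was 3.37, 3.15 and 4.42. The shares that changed were lower away from edges. Beyond 5 kb, 14.1% of het bases were less closed at 2 months, 11.7% in the knockout and 5.32% in both. Among all het bases these shares were 22.3%, 19.4% and 10.9%. A ratio can be higher where the shares are lower, and no level without change was simulated for these settings. The higher ratios thus do not show closer agreement. The correlation of window changes was 0.778 in windows of 500 kb, 0.902 in windows of 5 Mb, 0.751 in alternate blocks and 0.697 without bases within 5 kb of an edge. The slopes were 0.454, 0.495, 0.446 and 0.408. The cause of these differences in correlation and slope was not tested.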

Other observations

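The regions in this paragraph were chosen after their values had been seen. A few places were more open in the knockout than in both other groups. On chromosome 12 from 28900001 to 29000000, all 100 kb were euch in the knockout, against 8 kb in P14 wild-type and 6 kb in 2-month hepatocytes. On chromosome 11 from 96000001 to 96300000, euch covered 268 kb in the knockout, 156 kb in P14 wild-type and 70 kb in 2-month hepatocytes, and het covered 14, 130 and 204 kb. On chromosome 16 from 71600001 to 71700000 the knockout alone was closed, with an openness score of -0.78 against 0.6 and 0.96. Such places were rare. Of 24722 autosomal windows of 100 kb, the knockout score was more than 0.5 above both other groups in 145 and below both in 120. The 2-month score was above both in 986 and below both in 1051, and the P14 wild-type score was above both in 1065 and below both in 517. Among windows of 1 Mb, openness scores spread more widely with age. Their standard deviation was 0.403 in P14 wild-type, 0.458 in P14 knockout and 0.525 in 2-month hepatocytes. Windows with a score under -0.5 numbered 330, 458 and 572, and those above 0.5 numbered 268, 363 and 469.

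The tests of calling noise, of contrast and of a bias in the P14 wild-type libraries were chosen after the parallel changes had been seen. A test of that bias by the slope on X, chosen beforehand, was dropped because simulated maps gave nearly the same slope with and without an effect. The test of short domains was chosen beforehand, except that the flanks as background replaced a genome-wide level afterwards.

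Windows of 1 Mb moved in the same direction with age and in the knockout. Calling noise over a few kb in the shared P14 wild-type map is a poor candidate explanation. Changes from alternate blocks of 20 kb that share no base still correlated at 0.751 (0.729 to 0.772). Many domains are longer than a block, with an N50 in that map of 46 kb for het and 52 kb for euch. Noise over whole domains enters both sets of blocks, so it stays open. A lower contrast of that map alone would keep the order of the windows, yet P14 and 2-month wild-type scores correlated at only 0.801 (0.782 to 0.822). Contrast was thus not the only difference between these maps. Noise or real change on top of it would lower this correlation too, so a part played by contrast stays open. If it were unrelated to the age change, a bias of the P14 wild-type libraries alone would give 2 unrelated steps. These are the steps from wild type to knockout and from knockout to 2 months. Over alternate blocks they correlated at 0.426 (0.381 to 0.468), which argues against such an unrelated bias as the whole cause. A bias along the same regions as the age change could give this correlation too, and stays open. A technical difference graded over the 3 maps, with the knockout between the others, was not tested and stays open, and so does an early, partial form of the age change in the knockout, which may be the biological explanation. The mix of sexes was not tested on autosomes and stays open too. The knockout and 2-month pools both had 3 females of 5, and the P14 wild-type pool had 2.

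P14 wild-type domains were more numerous and shorter. If calls in that map had switched at random, the 16903 short domains (at most 10 kb) that were missing at 2 months and had flanks to compare would have kept their class in the knockout no more often than their flanks. They had that class in 31.7% of bases against 9.85% in the flanks, a difference of 21.9 percentage points (21.2 to 22.6), which argues against random switching as the only source. Noise at places whose signal lies near the calling threshold in every map could give the same excess and stays open, as does a difference in sequencing depth, which the maps do not show. Joining of domains with age may be a biological explanation, but it is a hypothesis that no test here decides.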
